A study of Mus musculus with 12 samples.

How the data were processed

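The series holds 12 RNA sequencing libraries of mouse paw fibroblast cultures in 4 groups of 3, and the groups were taken from the titles in the labels. Per the labels' protocols, polyadenylated RNA was prepared with a stranded kit. Per the submitters' processing notes, the tools were cutadapt 1.18, STAR 2.6.1c, featureCounts of Subread 1.6.1 and DESeq2 1.24.0, with the mouse genome build GRCm38. Their settings, the annotation release, the strand setting of the counting and whether the transformation was blind to the groups are not given in the sources used here. The deposited table holds log2 values, the authors' regularized log (rlog), for 55413 Ensembl genes, per the name and the values of the table. They run from -2.24 to 20.6, and 19136 genes are listed at 0 in every library. The regularized log shrinks differences of weakly expressed genes, so their differences are understated. It keeps no read counts, so the depth of each library is unknown and no count model or counting interval was used. Without the strand setting, overlapping antisense genes and near-identical gene copies have uncertain values.

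All 55413 identifiers matched a symbol, and where identifiers shared a symbol it stayed with the one of highest expression. Coordinates come from the GENCODE annotation (release M21) of GRCm38. Genes with a mean rlog value of at least 3 over the 12 libraries were kept, which left 16459. A model with 1 mean per group was fitted to all 12 libraries at once with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), so that the groups share an estimate of the spread. P-values were two-sided and adjusted over genes with the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. A gene is said to rise, fall or change only where it was called. Differences are given in log2 units with standard errors from this fit, and group means with their SD. An exact permutation test of 3 against 3 libraries cannot go below 0.1 and was not used.

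Before the data were examined, 42 gene lists were fixed, of which the 36 with at least 4 tested genes were tested. They were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, each adjusted over lists within a comparison. None of the mitochondrial transcripts listed is in the table. The rule for named genes was fixed at the same time. It took, per comparison, the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, leaving out predicted genes, then up to 3 called genes of each list with the largest difference. It added 23 genes reported whatever their result, and the 5 smallest p-values where fewer than 5 genes passed. Xist, Cdkn2a, the Y-linked genes and Cxcl5 were named in addition after their values had been seen, as were the lists of melanocyte lineage and fibroblast markers. Further melanocyte lists, 2 in number, were written before the values of their genes were looked at, the later one because the earlier one had not given the level set for it. No further list was tried.

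Shared vehicle libraries were allowed for by simulating unchanged groups 100 times, and the same was done for in vivo library 1 alone after the data were seen. In these simulations noise was drawn separately for each gene, so deviations shared by genes within a library were left out. Alternatives fixed in advance were no filter on low values, a minimum mean of 5, no variance trend, robust moderation, median-centred libraries, quantile normalization, array weights, only the libraries compared, the replicate number as a block, and each library left out in turn. Alternatives without the libraries rich in melanocyte transcripts were added after the data were seen, as were the tests of gene lists in the fit of only the in vitro and vehicle libraries, leaving out each library in that fit, and the replicate block for the correlation of the treatments. The procedure was tested on simulated data of 16459 genes, with the same spread for every group and noise drawn separately for each gene. The rates below therefore differ between comparisons by the random draw alone. They do not give the power or false calls in the real groups, whose spreads differed. For in vitro treated against vehicle it recovered 23.9%, 71.6% and 93.9% of genes changed by 1, 2 and 4 log2 units, with 4 false calls, and for primed against non-primed 32.8%, 65.7% and 90.9%, with 8. For in vivo treated against vehicle it recovered 32.8%, 68.7% and 92.4%, with 8 false calls, and for in vitro against in vivo 28.4%, 68.7% and 86.4%, with 1. In a simulation of 36 lists with 1 shifted by 1 log2 unit, camera called that list and 1 other.

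In lists that camera did not call, the median, the mean and the camera direction did not always have the same sign. This held for glycolysis, mTOR and cholesterol synthesis in primed against non-primed, and for mTOR and chondrocyte markers in vivo against vehicle and in vitro against in vivo. It also held for glycolysis, oxidative phosphorylation, skeletal muscle and Schwann cell markers in vitro against vehicle.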

Results

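Gene expression was measured by RNA sequencing in 12 libraries of fibroblasts grown out of collagenase-digested paws of BALB/c mice, an inbred laboratory strain. Monosodium urate (MSU) crystals, the crystals that form in gouty joints, had been injected into the paws. Primed paws (left) received crystals on day 0 and day 9, and non-primed paws (right) received them on day 9 alone, so that side and priming went together. RNA was taken on day 18, after 5 passages in culture, from cells pooled over 2 to 3 paws. The 4 groups held 3 libraries each: non-primed paws of vehicle-treated mice, primed paws of vehicle-treated mice, primed paws of mice given I-BET151 at 20 mg/kg per day from 1 day before the first crystals, and cells of primed paws exposed to 1 µM I-BET151 for 24 h in culture. I-BET151 is an inhibitor of the BET bromodomain proteins, which read acetylated histones. The values were regularized log2 (rlog) expression values, which keep no sequencing depth, so the depth of each library is unknown here. The labels do not say whether libraries of a group came from different animals, and p-values therefore measure the spread between these pooled cultures.

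Transcripts of pigment cells separated the libraries more than any group label did. Tyrp1 (chromosome 4, 80834123 to 80851719, GRCm38), which encodes a melanin synthesis enzyme, ranked 3, 3 and 9 among all genes in the libraries labelled non-primed 1, 2 and 3. It ranked 9 in each of the libraries labelled in vivo 2 and 3, and 12701 or lower in the other 7 libraries. The mean over 15 melanocyte lineage markers lay between 13.4 and 14.75 in these 5 libraries and between 5.44 and 6.33 in the other 7. Over 10 fibroblast markers, Col1a1, Pdgfra and Thy1 among them, the mean lay between 6.86 and 11.26 in the 5 libraries and between 14.74 and 15.7 in the other 7. Xist, the non-coding RNA of the inactive X chromosome, stood at 5.02 to 10.16 in the 5 libraries and at 13.68 to 14.5 in the other 7. Both marker lists were chosen after the values had been seen. The first principal component held 74.6% of the variance and divided the libraries in the same way, and the second held 13.9%. The library labelled in vivo 1 had a correlation across genes of 0.986 to 0.9918 with the in vitro libraries. The comparison of in vitro treated with primed vehicle libraries was the one with no melanocyte-rich library on either side.

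**Figure D1:**
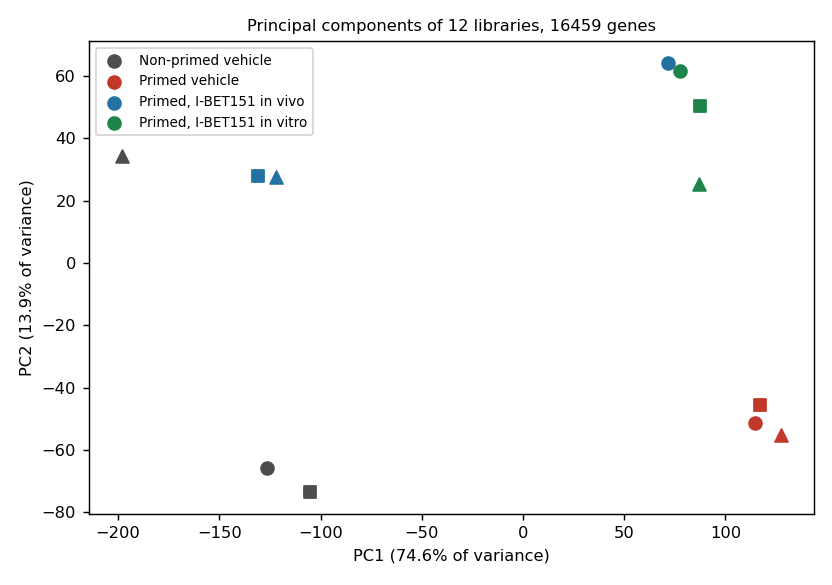
Principal component scores of the 12 libraries over 16459 genes, with PC1 (74.6% of the variance) on the horizontal and PC2 (13.9%) on the vertical axis. Colours are the 4 groups, and circles, squares and triangles are replicates 1, 2 and 3; the 3 non-primed libraries and in vivo libraries 2 and 3 lie at negative PC1 scores, and in vivo library 1 lies beside the in vitro libraries.

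**Figure D2:**
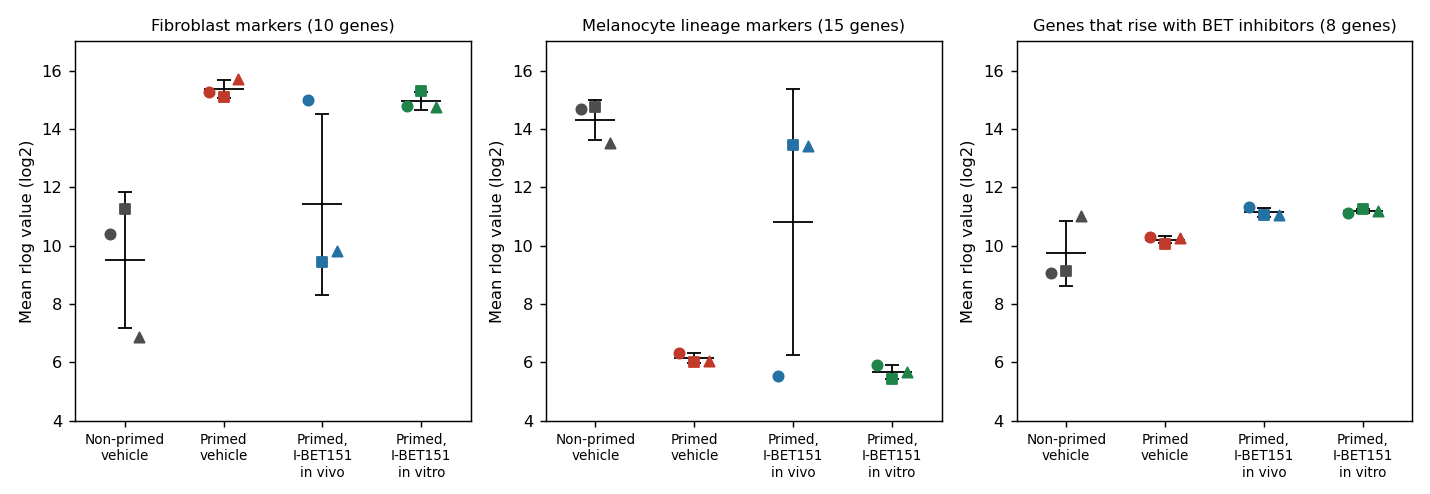
Mean rlog value (log2) in each library over 10 fibroblast markers, 15 melanocyte lineage markers and 8 genes known to rise with BET inhibitors. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), and the lines are the group mean ± SD (n = 3); in vivo library 1 lies at 5.54 for the melanocyte markers and in vivo libraries 2 and 3 lie at 13.46 and 13.4.

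Primed were compared with non-primed vehicle libraries to ask what an earlier crystal exposure left behind in cultured fibroblasts. Inflammatory mediators were far higher in the primed libraries. Cxcl3, a neutrophil-attracting chemokine, rose by 9.08 ± 1.17 log2 units (SE, n = 3 per group; adjusted p = 0.000861, limma), and Il1b, which encodes interleukin-1 beta, rose by 8.93 ± 0.72 from 1.59 ± 0.54 to 10.52 ± 1.62 (SD). Nos2, the inducible nitric oxide synthase, rose by 8.80 ± 1.08, Il6 by 8.13 ± 1.15 and Ccl2 by 7.44 ± 1.49. Pigment cell genes showed the largest falls. Tyrp1 changed by -12.46 ± 2.82, Dct, another melanin synthesis enzyme, by -12.21 ± 2.81, and Tyr, the tyrosinase gene, by -10.71 ± 2.39. All 15 melanocyte lineage markers fell and all 10 fibroblast markers rose in this comparison, in which each non-primed library was melanocyte-rich.

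Of the 33 cytokine and chemokine genes measured, 31 rose and none fell, with a median difference of 6.44 (camera adjusted p = 5.02e-11 with a preset correlation, and adjusted p = 0.536 with an estimated correlation). Il1a (8.75 ± 1.244) and Il1b showed large rises within the list. In the list of the NF-kB pathway and its targets 20 of 23 genes rose, among them Ptgs2, the inducible prostaglandin synthase (7.72 ± 1.37), Icam1 (6.53 ± 1.20) and Vcam1 (5.99 ± 0.93), both leukocyte adhesion molecules. Complement genes rose in 15 of 17 cases, with C3 at 6.98 ± 1.19 and Serping1, the C1 inhibitor, at 6.52 ± 1.43. Of 11 inflammasome genes 6 rose and 4 fell. The list was not called by camera with the preset correlation (adjusted p = 0.265), while fry called it as higher (adjusted p = 0.00353). Nlrp3, the sensor that MSU crystals engage, rose by 5.05 ± 0.43, and Gsdmd, whose product forms pores in the cell membrane, rose by 4.60 ± 0.58. Among 32 interferon-stimulated genes 16 rose and none fell, with Zbp1 at 7.07 ± 1.21 and Ifi44 at 6.69 ± 1.22. Without non-primed library 3, whose mean over this list was 7.19 against 10.02 and 10.53 in libraries 1 and 2, 9 of them rose and the median was 1.04 in place of 2.21. The libraries that carried these lower values, non-primed 1 to 3, had melanocyte marker means of 14.67, 14.75 and 13.52.

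Matrix genes moved the same way as the inflammatory lists. Of 41 collagens and matrix genes 37 rose (median 5.04), including Lum (7.84 ± 1.37), Dcn (7.51 ± 1.37) and the collagen cross-linking enzyme Lox (7.14 ± 1.55). Of 31 matrix proteases and inhibitors 21 rose, with the collagenase Mmp13 at 8.71 ± 1.49, the stromelysin Mmp3 at 8.65 ± 1.33 and Mmp10 at 8.24 ± 1.31. The myofibroblast list rose in 20 of 22 genes, with Acta2, smooth muscle actin, at 7.40 ± 1.74. Lining markers rose in 8 of 11 genes, with the lubricin gene Prg4 at 6.63 ± 1.45, and sublining markers rose in 10 of 14, with Thy1 at 6.96 ± 1.77. Fibroblast marker means were 10.39, 11.26 and 6.86 in the 3 non-primed libraries against 15.25, 15.11 and 15.7 in the primed ones.

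Cell cycle genes were lower in primed libraries. Of 35 measured, 33 fell and none rose (median -2.204), with Cenpf at -3.30 ± 0.45 and the proliferation marker Mki67 at -3.07 ± 0.51. The cell cycle mean lay between 12.87 and 13.17 in the melanocyte-rich libraries, in vivo 2 and 3 included. It lay between 10.66 and 11.29 in all others. In the list of p53 targets and senescence genes 13 of 19 rose and 2 fell, with the cell cycle inhibitor Cdkn2b at 5.64 ± 1.237. Oxidative phosphorylation genes fell in 21 of 38 cases and rose in 1, with Sdhb at -1.44 ± 0.27. NRF2 targets, genes of the oxidative stress response, rose in 14 of 16 cases, with Nqo1 at 4.27 ± 0.60. Macrophage markers rose in 12 of 15 genes (Cd14 7.37 ± 0.90), and all 5 osteoclast markers and all 4 adipocyte markers rose. Macrophage marker means lay between 3.33 and 6.55 in the melanocyte-rich libraries and between 8.12 and 10.18 in the others. Every non-primed library was melanocyte-rich, so list differences in this comparison cannot be told apart from that split. Tnfsf11, the osteoclast-inducing ligand RANKL, rose by 6.69 ± 1.14. Glycolysis was not called as a list (2 of 23 rose, 1 fell, adjusted p = 0.87), its median of 0.04 flipped to -0.03 with median-centred libraries and to -0.34 with quantile normalization, and Slc2a1, a glucose transporter, rose by 2.12 ± 0.57. Mtor and Hexim1 did not pass, with differences of -0.13 ± 0.14 and -0.71 ± 0.45. Without non-primed library 3, where Hexim1 stood at 14.26 against 12.19 and 12.25 in libraries 1 and 2, its difference was -0.03 ± 0.15.

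In all, 8528 of 16459 genes (51.8%) passed, 4754 higher and 3774 lower, and in 61.7% of genes the values of both groups did not overlap, where chance gives 10%. Adjusted over the list alone, 31 cytokine genes, 37 matrix genes and 18 interferon-stimulated genes rose and 33 cell cycle genes fell. Of 36 gene lists tested, 19 were called with the preset correlation (17 higher, 2 lower), 0 with an estimated one and 28 with fry. Quantile normalization changed the split to 3858 higher and 5680 lower, with the median of all genes moving from 0.05 to -0.24.

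Mice given I-BET151 were compared with vehicle-treated mice, both with primed paws, to ask what BET inhibition during the crystal exposures changed. Il1a, Il1b and Csf2 lay below 3 log2 units in all 3 libraries of treated mice. Il1a changed by -9.60 ± 1.244 log2 units (SE, n = 3 per group; adjusted p = 0.0016, limma), Il6 by -9.17 ± 1.15, Il1b by -8.87 ± 0.72 and Csf2, which encodes the growth factor GM-CSF, by -8.77 ± 0.82. Il6 (chromosome 5, 30013114 to 30019981) stood at 6.91, 5.18 and 5.36 in the 3 treated libraries and at 14.98 ± 0.33 (SD) in vehicle. Hexim1, an inhibitor of the elongation factor P-TEFb and a common reporter of BET inhibition, rose by 1.92 ± 0.45 (limma adjusted p = 0.0109). Brd2 rose by 1.70 ± 0.38. Of 8 genes that rise with BET inhibitors 3 rose and none fell, and the list was not called (camera adjusted p = 0.0986, fry adjusted p = 0.116). Pmel, a melanosome protein, showed the largest rise among genes whose groups did not overlap (6.76 ± 1.98), with 8.12 in in vivo library 1 and 17.66 and 17.56 in in vivo libraries 2 and 3.

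Cytokine and chemokine genes fell in 28 of 33 cases and rose in none (median -5.36, camera adjusted p = 3.81e-12, and adjusted p = 0.591 with an estimated correlation). Cxcl3 changed by -8.60 ± 1.17 and Ccl2 by -5.10 ± 1.49, while Cxcl12 (-3.85 ± 1.57, adjusted p = 0.0728) did not pass. Interferon-stimulated genes fell in 30 of 32 cases, with Ifi44 at -8.09 ± 1.22, Oasl2 at -7.20 ± 1.11 and Zbp1 at -7.03 ± 1.21. Of the NF-kB list 20 of 23 genes fell, with Tnip3 at -6.11 ± 0.64, Traf1 at -5.49 ± 0.60 and Ptgs2 at -5.35 ± 1.37. Complement fell in 10 of 17 genes (Cfb -4.88 ± 0.78, C3 -3.79 ± 1.19), and the inflammasome list held 7 falls and 2 rises, with Nlrp3 at -5.76 ± 0.43 and Gsdmd at -5.23 ± 0.58. Melanocyte marker means were 5.54, 13.46 and 13.4 in in vivo libraries 1, 2 and 3, so that 2 of the 3 libraries behind these falls were melanocyte-rich. Fibroblast marker means in the same libraries were 15, 9.44 and 9.81.

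Of 41 collagens and matrix genes 13 fell and none rose, with the matrix protein Tnc at -5.21 ± 1.66 and Lum at -5.05 ± 1.37, whereas Col1a1 (-4.04 ± 1.67, adjusted p = 0.0749) did not pass. Col1a1 stood at 18.39 in in vivo library 1 and at 11.8 and 12.36 in libraries 2 and 3. Matrix proteases fell in 12 of 31 cases, among them Mmp10 (-8.04 ± 1.31), Mmp13 (-7.67 ± 1.49) and Mmp3 (-7.01 ± 1.33). Myofibroblast genes fell in 16 of 22 cases, with Myl9 at -5.41 ± 1.40. With in vivo library 1 alone the medians were -0.54 for the myofibroblast list (-2.93 with all 3 libraries), 0.06 for collagens and matrix (-3.26), -0.42 for matrix proteases (-1.99) and -0.80 for osteoclast regulators (-3.42), and 1 gene of these 4 lists was called, a protease gene. The cytokine median was -4.19 (-5.36) with 7 of 33 genes called in place of 28, and that of interferon-stimulated genes -4.27 (-4.35) with 1 of 32 called in place of 30. The NF-kB median was -1.47 (-2.55) with 3 genes called in place of 20. Complement was at -0.80 (-2.83), macrophage markers at -1.59 (-3.23), NRF2 targets at -1.11 (-1.73) and cell cycle genes at 0.27 (1.497), with no gene of these 4 lists called. Of the osteoclast regulators 5 of 7 fell, with Tnfsf11 at -6.39 ± 1.14 and its decoy receptor Tnfrsf11b at -4.12 ± 0.94. Macrophage markers fell in 10 of 15 cases, with Cd14 at -5.87 ± 0.90. NRF2 targets fell in 13 of 16 cases, with Gsta3 at -4.90 ± 0.74. Cell cycle genes rose in 27 of 35 cases, with Mki67 at 2.31 ± 0.51. Mki67 stood at 13.1 in in vivo library 1 and at 15.36 and 15.43 in libraries 2 and 3.

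Over all genes, 6531 (39.7%) passed, 2946 higher and 3585 lower. With the preset correlation 20 lists were called (2 higher, 18 lower), with an estimated one 0 and with fry 21. Adjusted over the list alone, 29 cytokine genes, 31 interferon-stimulated genes and 13 matrix genes fell and 32 cell cycle genes rose. Quantile normalization changed the split to 4595 higher and 2967 lower, with the median of all genes at 0.19 in place of -0.05. With in vivo library 1 alone against vehicle, a choice made after the data were seen, 195 genes passed, Il1b (-8.71 ± 1.10), Csf2 (-8.70 ± 1.25), Nlrp3 (-5.68 ± 0.64) and Gsdmd (-4.21 ± 0.75) among them, and Hexim1 (1.71 ± 0.68, adjusted p = 0.188) did not. Leaving out a library in turn gave 4340, 3821 and 3378 genes without vehicle libraries 1, 2 and 3, and 9962, 2483 and 2435 without in vivo libraries 1, 2 and 3.

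Cells of primed paws exposed to I-BET151 in culture were compared with primed vehicle libraries to ask what 24 h with the inhibitor changed in cultured cells. The labels do not state whether the animals behind the treated cells had received vehicle. Il1b showed the largest fall among genes whose groups did not overlap, -7.97 ± 0.72 log2 units (SE, n = 3 per group; adjusted p = 0.0038, limma), from 10.52 ± 1.62 to 2.55 ± 0.81 (SD). Csf2 changed by -7.90 ± 0.82, Il1a by -7.39 ± 1.244, Mmp10 by -6.49 ± 1.31 and Gpr84, a receptor for medium-chain fatty acids, by -5.99 ± 0.61. Brd2 (chromosome 17, 34112023 to 34122634), itself a target of the inhibitor, rose by 2.01 ± 0.38, from 14.64 ± 0.03 to 16.65 ± 0.16. Melanocyte marker means were low on both sides (6.13 ± 0.17 in vehicle and 5.67 ± 0.23 in treated cells), and no marker of that list passed.

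The interferon-stimulated list had a median of -2.87. In it 4 of 32 genes fell over all genes tested and 31 when adjusted over the list alone (camera adjusted p = 4.57e-14, and adjusted p = 0.925 with an estimated correlation). Oas3 changed by -4.41 ± 0.86, Ifit3 by -4.29 ± 1.05 and Usp18 by -3.37 ± 0.76. Cytokine and chemokine genes had a median of -2.28, with 6 of 33 falling over all genes and 16 over the list alone (camera adjusted p = 9.85e-09, and adjusted p = 0.925 with an estimated correlation). Il6 (-4.60 ± 1.15, adjusted p = 0.0511) just missed the threshold, and Ccl2 (-1.28 ± 1.49) did not pass either. In the NF-kB list Tnip3 (-3.71 ± 0.64) and Traf1 (-3.35 ± 0.60) fell, 2 of 23 over all genes and 4 over the list alone (camera adjusted p = 0.000634, and adjusted p = 0.925 with an estimated correlation). Nlrp3 (-3.67 ± 0.43) and Gsdmd (-2.83 ± 0.58) fell within the inflammasome list, which was not called. Genes that rise with BET inhibitors were called as higher (camera adjusted p = 0.024, and adjusted p = 0.925 with an estimated correlation), with 1 of 8 passing over all genes, Hist1h2bk at 1.35 ± 0.32, and Hexim1 at 1.78 ± 0.45 (adjusted p = 0.0509).

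Structural and lining genes gave no calls as lists in this comparison. None of 41 collagens and matrix genes passed (median -0.06), and Col1a1 differed by 0.12 ± 1.67. Prg4 differed by 0.64 ± 1.45, Thy1 by -0.18 ± 1.77 and Timp1 by 0.07 ± 1.13. In a fit of only the 6 libraries compared, the standard errors were 0.25, 0.33 and 0.23, and 0.37 for Col1a1, and none of the 4 genes passed. In that fit 1 of the 41 collagens and matrix genes rose and 5 fell, 4 of 31 matrix proteases rose and 8 fell, and 2 of 14 sublining markers rose and 5 fell, with none of these lists called by camera. In the fit of all 12 libraries none of 35 cell cycle genes and none of 15 macrophage markers passed, and with the 6 alone 1 cell cycle gene rose and 1 macrophage marker fell. In the mTOR list the sestrins Sesn3 and Sesn1, which restrain mTOR signalling, rose by 1.55 ± 0.27 and 1.14 ± 0.25. The lactate transporter Slc16a1 rose by 1.44 ± 0.35, the only call among 23 glycolysis genes. Among the largest rises over all genes were Fam222a (3.36 ± 0.75), Ankmy1 (3.29 ± 0.60) and Zfp541 (3.01 ± 0.60).

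Over all genes, 743 (4.51%) passed, 289 higher and 454 lower, and 4 lists were called with the preset correlation (1 higher, 3 lower), 0 with an estimated one and 0 with fry; quantile normalization gave 573 higher and 582 lower with the median of all genes at 0.08. Values of both groups did not overlap in 48.4% of genes, against 49.1% for in vivo treatment. The spread was shared over all 12 libraries, the melanocyte-rich ones included. With only the 6 libraries compared in the fit, 4983 genes passed (2207 higher, 2776 lower), all 743 among them with the same sign, and the standard errors shrank: Il6 (-4.60 ± 0.65), Hexim1 (1.78 ± 0.13), Mmp13 (-4.92 ± 0.56), Ccl2 (-1.28 ± 0.26) and Acta2 (-0.96 ± 0.10) then fell or rose past the threshold, and Mmp3 (-2.62 ± 0.85, adjusted p = 0.0567) did not. In list tests of that fit, added after the data were seen, 7 of 8 genes that rise with BET inhibitors rose, 31 of 32 interferon-stimulated genes fell, and the myofibroblast list was called as lower with 12 of 22 genes falling (camera adjusted p = 3.88e-05, and adjusted p = 0.483 with an estimated correlation). In the fit of all 12 libraries, leaving out vehicle libraries 1, 2 and 3 gave 244, 30 and 34 genes, and leaving out in vitro libraries 1, 2 and 3 gave 23, 12 and 367.

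**Figure D3:**
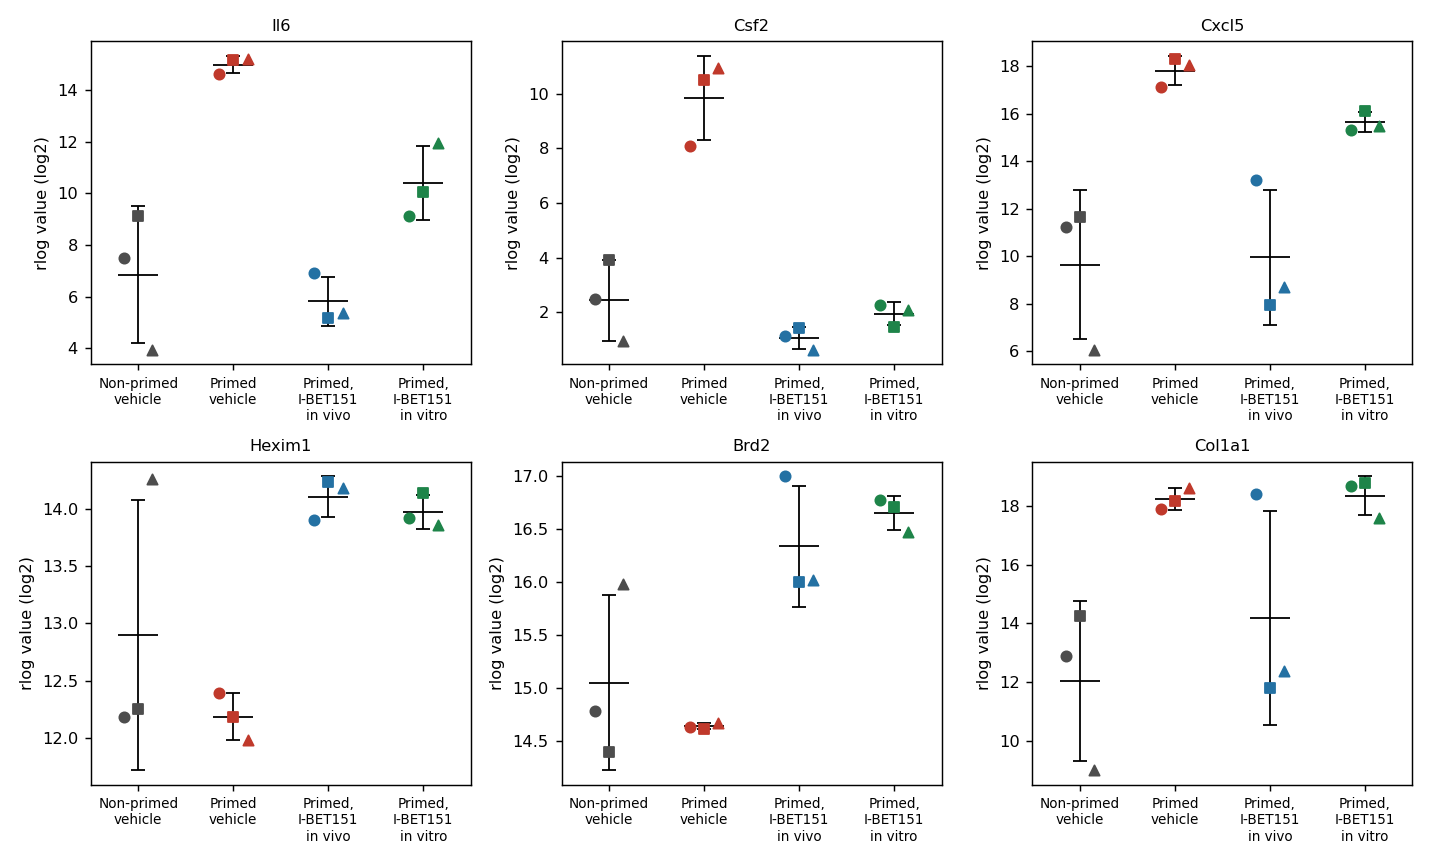
Rlog values (log2) of Il6, Csf2, Cxcl5, Hexim1, Brd2 and Col1a1 in each library of the 4 groups, with vertical axes that do not start at 0. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), and the lines are the mean ± SD (n = 3); Hexim1 lies at 12.19, 12.25 and 14.26 in the 3 non-primed libraries and between 11.98 and 12.39 in the primed vehicle ones. Cxcl5 was picked for the plot after its values were seen.

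Treatment in culture and in the animal were compared directly, which tests whether both effects against the same vehicle libraries differed. No gene passed with limma, although 5341 had an unadjusted p under 0.05. Csf3, a neutrophil growth factor, was 4.43 ± 0.67 log2 units higher in the in vitro libraries (SE, n = 3 per group; adjusted p = 0.122, limma) and Adam23 1.87 ± 0.26 higher. They were among the 5 genes with the smallest p, and all of these failed the threshold. Il6 differed by 4.57 ± 1.15, Ccl2 by 3.82 ± 1.49 and Mmp3 by 4.39 ± 1.33, while Hexim1 (-0.13 ± 0.45), Brd2 (0.31 ± 0.38) and Brd3 (-0.01 ± 0.10) differed by less than their standard errors. As lists, 24 of 36 were called with the preset correlation, 22 of them higher in vitro, and 0 with an estimated correlation. Collagens and matrix genes had a median of 2.65 (camera adjusted p = 3.69e-08, and adjusted p = 0.570 with an estimated correlation), cytokines 3.06, macrophage markers 3.10 and cell cycle genes -1.30. Adjusted over the list alone, 22 of 33 cytokine genes, 14 of 15 macrophage markers and 0 of 41 matrix genes were higher and 31 of 35 cell cycle genes lower. These lists moved with the melanocyte markers, whose means were 10.8 ± 4.56 (SD) in vivo and 5.67 ± 0.23 in vitro. Without in vivo library 1, 8085 genes passed, and with that library alone in the in vivo group none did.

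**Figure D4:**
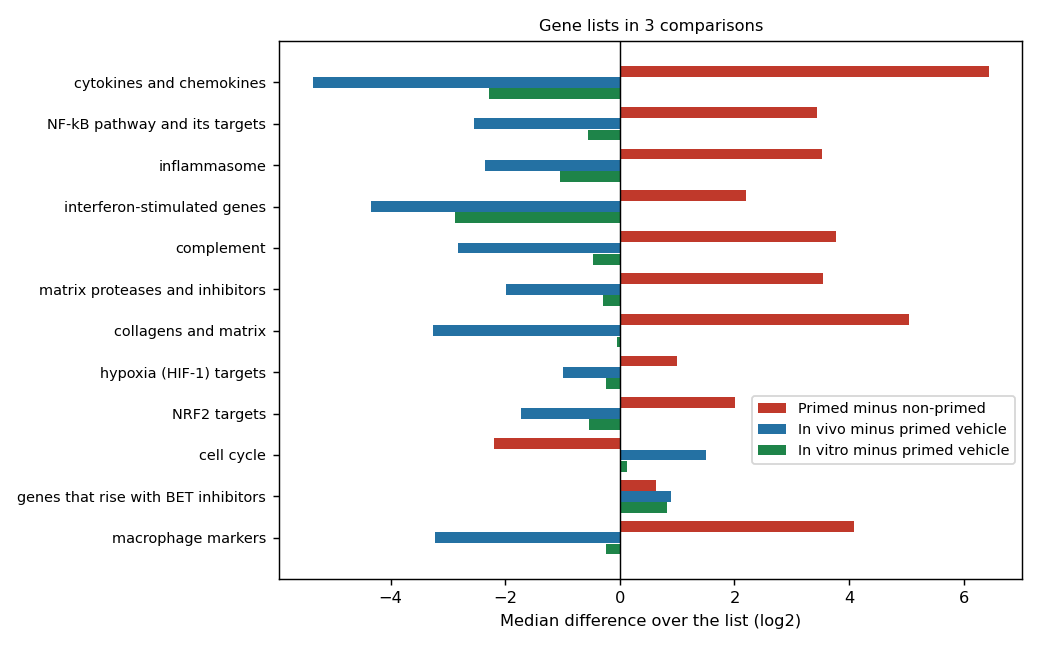
Median log2 difference over the tested members of 12 gene lists in 3 comparisons: primed minus non-primed, in vivo treated minus primed vehicle, and in vitro treated minus primed vehicle. Bars start at 0 and carry no error; cytokine and chemokine genes have medians of 6.44, -5.36 and -2.28, and collagens and matrix genes 5.04, -3.26 and -0.06.

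Genes that differed between primed and non-primed libraries were followed into the treated groups. Of the 8528 priming genes, 8421 (98.75%) lay on the opposite side of vehicle in the in vivo libraries, 5181 of them past the threshold, with a median 72.2% of the priming difference. In the in vitro libraries 6118 (71.74%) lay on the opposite side, 535 past the threshold, with a median of 18.5%. Il1b changed by 8.93 with priming, -8.87 in vivo and -7.97 in vitro, whereas Col1a1 changed by 6.18 ± 1.67 with priming and differed by 0.12 in vitro. Because both differences share the primed vehicle libraries, simulated unchanged groups already gave 56% (SD 0.555 and 0.514 over 100 simulations). These simulations drew noise separately for each gene, from the spread of the fit of all 12 libraries. They left out deviations that genes share within a library, so their SD is no measure of how far real unchanged groups vary. With in vivo library 1 alone, a choice made after the data were seen, the in vivo share was 68.8%, against 53.13% (SD 0.547) in simulated unchanged groups of that size. The 3 non-primed libraries and in vivo libraries 2 and 3 shared high melanocyte marker means (13.4 to 14.75, against 5.44 to 6.33 in the other 7). The share in vivo thus includes what these 5 libraries have in common. Non-primed library 3 also carried the response of genes that rise with BET inhibitors, although its label names no inhibitor. Without that library the share was 90.7% in vivo and 65.88% in vitro.

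The in vivo and in vitro effects had a Pearson correlation of 0.689 and a Spearman correlation of 0.640 across 16459 genes, which are not independent replicates. Simulated unchanged groups against the same vehicle libraries gave a Pearson value of 0.4999 ± 0.0117 (SD). Here too the SD leaves out deviations shared across genes, so the distance from the simulated value was not read as a test. The covariance was 0.916 against a simulated 0.129, a difference of 0.787, and 74.93% of genes had the same sign against 66.67% in the simulation. Of the genes that fell, 416 did so in both treatments, with Il1b, Csf2, Il1a, Nlrp3 and Gsdmd among them, where independent lists of these sizes would share 98.89. Of the genes that rose, 268 did so in both, with Brd2, Sesn1 and Sesn3 among them, against 51.73 for independent lists. With 3 vehicle libraries the controls could not be split in 2 sets with a spread of their own, and part of the excess may come from their being shared. With in vivo library 1 alone the correlation was 0.925, against 0.354 ± 0.0123 (SD) in simulated unchanged groups of that size. That library was picked after its values were seen and lay beside the in vitro libraries. The choice alone thus favoured a high value, which adds no evidence that both effects agree. Without in vivo library 1 the correlation was 0.558.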

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

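All tests of in vivo library 1 were chosen after its values had been seen; the comparison of the treatments was fixed before the data were examined. In vivo and in vitro effects against the same vehicle libraries differed for 24 of 36 gene lists in camera with the preset correlation, a difference between groups under the same contrast. With limma 0 genes passed (5341 at an unadjusted p under 0.05), as did 0 lists with an estimated correlation and 2 with fry (the NF-kB and hindlimb lists). Cytokine, collagen and macrophage lists were higher in vitro by medians of 3.06, 2.65 and 3.10, and the cell cycle list was lower by -1.30, while the list of genes that rise with BET inhibitors differed by 0.01, which flipped to -0.03 with median-centred libraries and to -0.15 with quantile normalization. The collagen mean was 13.67 in in vivo library 1, 9.12 and 9.42 in in vivo libraries 2 and 3, which were rich in melanocyte transcripts, and 13.18 to 13.8 in vitro, and the cell cycle mean was 11.27, 12.88 and 12.87 against 10.76 to 11.29. With in vivo library 1 alone 11 lists were called.

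The library labelled in vivo 1 stood with the in vitro libraries and apart from in vivo libraries 2 and 3. The in vitro libraries correlated with one another at 0.9851 or more and with in vivo libraries 2 and 3 at 0.8941 at most, a gap of 0.091. No in vitro library thus resembled in vivo libraries 2 and 3. The gap cannot decide on a swap of labels with an in vivo culture poor in melanocyte transcripts, which could also lie near the in vitro libraries. Fewer melanocyte-lineage cells in in vivo library 1 alone may account for where it stood and stay open. Without the melanocyte genes its lowest correlation with in vitro libraries exceeded its highest with primed vehicle libraries by 0.0358. Leaving those genes out moved neither correlation, and treated cells without melanocytes would lie near the in vitro ones too. A single wrong label, or an exchange with a sample outside the series, may account for the pattern, as the lowest correlation of in vivo library 1 with in vitro libraries exceeded their own lowest by 0.0009. A real effect of treatment in the animal that resembles treatment in culture stays open as well, untested, since the design names it.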

How the results depend on the processing

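The comparisons, the thresholds and most alternatives were fixed before the data were examined; the alternatives with in vivo library 1 alone or with 7 fibroblast-rich libraries, the gene lists and the leaving out of libraries in the fit of the 6 in vitro and vehicle libraries, and the replicate block for the correlation were chosen after seeing the data, and where no cause is given below, the cause was not tested. Primed against non-primed gave 6706 to 10191 genes over all alternatives. In vivo treatment gave 12582 genes with array weights, 3950 with only the 6 libraries compared and 195 with in vivo library 1 alone (1 library in that group, assumed to vary like the others), and 2435 to 9962 leaving out each library in turn, the lowest without in vivo library 3 and the highest without in vivo library 1. In vitro treatment gave 1180 genes with no filter, 470 at a mean of at least 5, 1155 with quantile normalization, 6326 with array weights, 4983 with only its 6 libraries and 4989 with 7 fibroblast-rich libraries, and 12 to 367 leaving out each library (without in vitro libraries 2 and 3). With its 6 libraries alone, leaving out each gave 2520 to 4612. In vitro against in vivo gave 0 genes with limma (5341 at an unadjusted p under 0.05), 1 with no filter, 12243 with array weights and 0 to 8085 leaving out each library, the highest without in vivo library 1. With an estimated correlation 0 lists were called in each of the 4 comparisons; fry called 0 for in vitro treatment (13 with only its 6 libraries, where camera called 5, or 0 with an estimated correlation) and 2 for in vitro against in vivo, and in vivo library 1 alone gave 8 lists against vehicle and 11 against in vitro. Priming genes on the opposite side in vivo were 68.8% with in vivo library 1 alone and 90.7 to 99.87% leaving out each library, and in vitro 65.88 to 77.38%. The correlation of both treatments was 0.8757 against the non-primed libraries, 0.9249 with in vivo library 1 alone (simulated unchanged groups 0.3542) and 0.558 to 0.7712 leaving out each library. No called named gene changed sign; among those not called 35 values, over 25 differences, had the other sign and none of these passed. In the 4 comparisons 88, 435, 175 and 0 values lost the threshold and 2, 16, 29 and 48 gained it, while 1801, 1530, 649 and 398 did neither. Quantile normalization moved the median of all genes to -0.237, 0.186, 0.0788 and -0.124 and flipped the ribosomal list with priming from 0.223 to -0.204. The rlog values keep no depth, so its effect was not examined.

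Replicate numbers did not pair the libraries: 4 of 18 pairs with the same number correlated over 0.1 (range -0.435 to 0.369), and 3 of 12 libraries matched best with their own number. With the replicate number as a block, 8141, 5977, 173 and 0 genes and 19, 20, 4 and 24 lists were called, and 99.1% and 72.2% of priming genes lay on the opposite side.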

Other observations

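The fixed gene lists, their comparisons, the other splits and both further melanocyte lists were set before their results were seen, and the other tests that weigh explanations were chosen after. Genes that mark limb position differed between libraries of the same kind of tissue. Pitx1, a hindlimb regulator, stood at 8.83, 9.56 and 9.09 in the primed libraries and at 3.79, 4.15 and 2.2 in the non-primed ones, and Hoxc10 rose by 5.63 ± 0.59 and Hoxc11 by 5.28 ± 0.56 log2 units with priming (n = 3 per group). Tbx4, the hindlimb T-box gene, lay between 9.95 and 11.48 in all 12 libraries, and Tbx5, its forelimb counterpart, at -1.22 to -0.53. Hindlimb genes fell in vivo in 5 of 6 cases, with Hoxc10 at -3.46 ± 0.59. Forelimb genes moved the same way, 3 of 4 rising and 1 falling with priming (median 2.69) and 2 of 4 falling in vivo (median -2.32). Camera did not call them as a list, while fry did (adjusted p = 0.00526 with priming and 0.0118 in vivo). Hindlimb means lay between 3.1 and 5.03 in the 5 libraries high in melanocyte markers and between 6.21 and 7.96 in the other 7.

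Cell cycle inhibitors and sex-linked transcripts also differed between libraries. Cdkn2a stood at 11.24 to 12.47 in the primed, in vitro and in vivo 1 libraries, at 9.01, 9.05 and 3.6 in non-primed libraries 1, 2 and 3 and at 8.1 and 8.75 in in vivo libraries 2 and 3. Eif2s3y, Uty and Ddx3y, genes of the Y chromosome, stood at 6.39, 5.46 and 4.6 in in vivo library 2, at -0.43, 0.16 and 1.88 in non-primed library 2 and below -0.7 in the other 10 libraries. The macrophage marker Adgre1 rose by 5.72 ± 1.176 with priming.

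In 5 libraries, non-primed 1 to 3 and in vivo 2 and 3, melanocyte transcripts were abundant and fibroblast markers low. Xist differed by 6.25 ± 1.34 between primed and non-primed libraries, which argues against a state of the same fibroblasts only if such a state leaves Xist unchanged. That premise was not tested, and the bound for Xist was set after its values had been seen. Of the 6 non-primed and in vivo libraries 1 lay under a melanocyte mean of 8, so that by count alone no exchange of labels among them gives a group of 3 without such transcripts. Melanocyte-lineage cells in these libraries may account for the pattern, but the test planned for it came out against it: the median of a second list was -0.47 in the lowest of the 5 libraries minus the highest of the other 7, under the 0.5 set beforehand. That bound was judged unsuitable only after the result, because a median of levels is set by genes that every library expresses, and gene by gene the list had a median difference of 3.14 (8 of 13 genes over 1, 3 under -1); a later list of 6 genes, added for this reason, gave 0.69 and left it open. An effect of priming or treatment on which cells grew out stays open as well, untested.

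Non-primed library 3 carried the response of genes known to rise with BET inhibitors, although its label names no inhibitor. Hexim1 was 2.01 higher there than in the higher of the other non-primed libraries, while its melanocyte mean was the lowest of the 3 (13.52 against 14.67 and 14.75). Its fibroblast and macrophage means were the lowest too (6.86 against 10.39 and 11.26, and 3.33 against 5.61 and 6.55). A larger share of melanocyte-lineage cells in it thus stays possible. The mean over the genes that rise with BET inhibitors was 11.004 there and 9.053 and 9.137 in non-primed libraries 1 and 2. In the fibroblast-rich primed vehicle libraries it lay between 10.053 and 10.281. More melanocyte-lineage cells like those of non-primed libraries 1 and 2 would lower this mean. For this list, these values, compared after they were seen, argue against a larger share as the cause of the response. The correlation of in vivo library 1 with in vitro libraries lay 0.1158 above that with non-primed libraries 1 and 2. This cannot decide on an exchange with in vivo library 1, since those non-primed libraries were melanocyte-rich and in vivo library 1 was not. Contact with I-BET151 or a wrong label may account for the response in non-primed library 3. The list lay within 0.06 of in vivo libraries 2 and 3, against 1.87 or more to the other non-primed libraries. The difference between non-primed library 3 and in vivo library 3 over 3906 highly expressed genes had a median absolute deviation of 0.0719. Scaled to match an SD, this deviation was the smallest of all pairs. By correlation over all tested genes the pair stood at 0.98, below others such as in vivo libraries 2 and 3 at 0.9962. Without counts the deviation cannot be set against sampling noise.

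Other splits of the 6 libraries of each comparison numbered 10 with the real one, too few for a share under 0.05. As many genes as the real split came from 1 split for primed against non-primed (8528, highest other 1), 1 for in vivo treatment (6531, highest other 3), 1 for in vitro treatment (743, highest other 0) and 10 for in vitro against in vivo (0 by limma, highest other 0, with 5341 at an unadjusted p under 0.05 in the real one).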
